A study of Homo sapiens with 60 samples.

How the data were processed

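Gene expression was measured on 60 GeneChip Human Gene 1.0 ST arrays hybridised with RNA from cultured synovial fibroblasts of 1 individual with rheumatoid arthritis. Per the labels' protocols, the cells were held in medium of low serum before TNF, IL-17A or both were added, each at 1 ng/mL. The labels place the arrays in 5 arms (untreated at 0 h, media, IL-17A, TNF and TNF plus IL-17A) and 9 time points, which gives 30 groups of 2 arrays. Per the series design text the 2 arrays of a group are technical replicates, so p-values of limma models fitted to single arrays measure only the spread between technical replicates of cells from 1 donor. None of the p-values below speaks about the spread between donors or separate experiments.

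The deposited value table holds 1 log2 expression value per probe set and array, for 33,297 probe sets. Per the submitters' processing notes the authors used RMA, which corrects background, normalizes between arrays and summarises probes on a log2 scale. Its version and the software are not given in the sources used here. The log base is not written in the deposited table and was taken as log2 from the use of RMA and from the values, which ran from 1.66 to 14.1 with array medians of 6.40 to 6.52. RMA's normalization sets the arrays to a common distribution, so a change of total RNA per cell could not be seen. Low signals are compressed by background signal, so changes of dim genes are understated. Arrays have no read depth. Their number limits the precision, and no background measurement per probe set was used here.

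Probe sets were named with the platform annotation supplied for the array. Of the 33,297 probe sets, 19,460 had 1 gene symbol, 1754 had several and 12,083 had none. Of those with 1 symbol, 19,429 matched a current gene record and 0 symbols were changed. Probe sets with several symbols or none were tested separately and not named. For the 769 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 18,417 genes. No genome was used, so no coordinates are given.

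The values were analysed as deposited. A linear model with 1 mean per group was fitted to all 60 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes without an intensity trend) in R 4.3.3, so that all groups shared 1 estimate of the spread, with 30 residual degrees of freedom and a prior of 6.08. The p-values were two-sided and were adjusted by the Benjamini-Hochberg method over 18,417 genes within each comparison. A gene was called, and is said to have risen or fallen, at an adjusted p below 0.05. Without any change, a share of about 0.05 of the 18,417 genes would have an unadjusted p below 0.05. Counts of such genes are therefore not evidence of changes by themselves. Changes are differences of log2 values with their standard error (SE) from this model. TNF, IL-17A and TNF plus IL-17A were each compared with media as the mean over 1, 4, 8, 18 and 24 h, the 5 times that all 4 arms share, with 10 arrays per arm. TNF plus IL-17A was compared with TNF over all 8 times that hold both arms, with 16 arrays per arm, and TNF with IL-17A over 7 times. The departure from additivity was the change with TNF plus IL-17A against media minus the sum of the changes with TNF and with IL-17A, on the log2 scale, over the same 5 times. Each comparison except TNF with IL-17A was also made at single times, with 2 arrays per arm, and media at each time was compared with untreated cells at 0 h. Late effects were compared with early effects as 18, 24 and 72 h minus 1, 2 and 4 h for IL-17A added to TNF, and as 18 and 24 h minus 1 and 4 h for TNF against media. Comparisons that share arrays were not correlated or overlapped with each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

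The model, the comparisons, the rule for named genes, 37 gene lists and all alternatives except those said to have been added were fixed before the data were examined. The lists covered chemokines of 3 kinds, interleukins and colony-stimulating factors, signalling genes of the TNF and IL-17 receptors, NF-kB feedback genes, transcription regulators and receptors studied with these data, immediate early genes, interferon-stimulated genes, antigen processing, adhesion, metalloproteinases, matrix, contractile genes, glycolysis and hypoxia, cholesterol synthesis, cell cycle, zinc handling, oxidative stress, the unfolded protein response, heat shock, apoptosis, prostaglandins, complement, Wnt and BMP genes, growth factors, and markers of 10 cell types. They held 572 entries, of which 537 were measured. The other entries were not analysed here. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with adjustment over all lists and 5 comparisons. The test was repeated with a correlation estimated per list. For each list the number of called members was also counted with p-values adjusted over the list alone.

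Named genes needed exactly 1 symbol. They were the 8 largest rises and 4 largest falls among called genes in TNF against media, IL-17A against media, TNF plus IL-17A against TNF and the departure from additivity. At each single time of TNF plus IL-17A against TNF, and at 1 and 72 h of TNF against media, they were the 2 largest rises and the largest fall. For each list they were the 4 measured members with the largest absolute change, for late against early effects the 3 largest in each direction, and for media at 72 h the 3 largest rises and 3 largest falls. Genes that vary with sex were left out.

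Alternatives were an intensity trend with a robust prior, a filter that kept 10,603 genes above the array median on at least 2 arrays, the mean of a gene's probe sets, median centring, quantile normalization, array weights, the estimated correlation for lists, a fit to only the groups compared, untreated cells at 0 h as the control, the replicate number as a term, and each array left out in turn. In a further alternative the arrays of a group were averaged and the error was the spread of an arm's effect between times. An effect that changes with time raises this error, so a call lost there does not show that the effect was absent. After the data were seen, a mean without the times at which a group had array weights below 0.5 was added. These groups were TNF at 24 h and TNF plus IL-17A at 2, 8 and 72 h, 8 arrays in all, and these arrays were also left out of the error estimate.

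The pipeline was tested on simulated data for 18,417 genes with 50 genes changed by each of 4 sizes. For TNF plus IL-17A against TNF over 8 times, 86% of changes of 0.25 and 100% of those of 0.5 or more on the log2 scale were recovered, with 10 false calls among 203. For IL-17A against media the shares were 82% and 100%, with 8 false among 199. At 24 h alone, TNF plus IL-17A against TNF recovered 16% of changes of 0.25, 68% of 0.5 and 96% of 1, and the departure from additivity recovered 0%, 20% and 92%. In the simulated list test, 2 of 100 random lists had a p below 0.05. The simulated noise was independent between genes, whereas the interferon-stimulated genes had an estimated correlation of 0.46. The simulation therefore does not show how the list test or the false calls behave with correlated genes.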

Results

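Synovial fibroblasts are the connective tissue cells of the joint lining, and TNF and IL-17A are inflammatory cytokines made by immune cells in the inflamed joint. The series followed how such fibroblasts, cultured from 1 individual with rheumatoid arthritis, responded over time to each cytokine at 1 ng/mL and to both together. The 60 arrays fell into 30 groups of 2. Untreated cells were taken at 0 h, cells in media at 1, 4, 8, 18, 24 and 72 h, cells with IL-17A at 1, 2, 4, 8, 12, 18 and 24 h, and cells with TNF or with TNF plus IL-17A at the same 7 times and at 72 h. Values are log2 expression after RMA by the authors, and 18,417 genes were tested.

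The 2 arrays of a group correlated at 0.993 to 0.998, and the SD of their difference had a median of 0.163 over the groups (0.134 to 0.258). For 36 of the 60 arrays the nearest array was its own replicate. Limma array weights fell below 0.5 for 8 arrays, those of TNF at 24 h and of TNF plus IL-17A at 2, 8 and 72 h. The 2 arrays of a group had the same weight, so the weights describe the spread within a group and not which array deviates. Media at 8 h lay just above the limit (0.5001).

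The first comparison asked which genes responded to TNF alone. Chemokine genes showed the largest rises over 1 to 24 h. CXCL8, which attracts neutrophils, rose by 6.29 ± 0.07 (log2 ± SE, n = 10 arrays per arm), CCL20 by 5.39 ± 0.11, the interferon-inducible chemokine CXCL10 by 5.38 ± 0.12 and CCL5 by 5.10 ± 0.06. The ion channel gene TRPA1 rose by 4.64 ± 0.08, PTGS2, which encodes the inducible cyclooxygenase, by 4.54 ± 0.06, the antiviral gene RSAD2 by 4.36 ± 0.10 and GBP4, an interferon-inducible GTPase gene, by 4.11 ± 0.08. The largest falls were in SLC14A1, a urea transporter gene (−2.64 ± 0.05), the chemerin receptor gene CMKLR1 (−2.38 ± 0.05), the alcohol dehydrogenase gene ADH1B (−2.22 ± 0.07) and TRIB2 (−2.07 ± 0.05). ADH1B rose in the media control itself, by 1.66 at 18 h and 3.04 at 72 h against untreated cells at 0 h. The 8 rising genes had higher values with TNF at 6 of 6 times, except RSAD2, which was higher at 5 of 6, and the 4 falling genes were lower at all 6.

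In total 8398 genes were called with TNF, 2957 higher and 5441 lower, and 346 rose and 73 fell by at least 2-fold. The split was 4221 higher and 4337 lower after median centring of the arrays, and 3220 and 5382 after quantile normalization. With the spread of the effect between times as the error, 2032 genes were called, and SLC14A1 and ADH1B were no longer called. Among list members given below, BMP6, ELF3, IGF1, MX2, SELE and STAT3 also lost their call with that error. So did the list members C2, C3AR1, IGFBP5, MSMO1, MT1F, MT1M, MYLK and PFKFB3, whose changes with TNF are not given here.

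All 17 measured genes of NF-kB feedback and family members rose with TNF (median 1.57, camera adjusted p = 8.0e-26), among them the inhibitors TNFAIP3 (3.55), TNIP3 (2.58) and NFKBIA (2.44). With an estimated correlation camera gave this list an adjusted p of 0.00016. For this and the following lists the counts adjusted over the list alone were the same unless given. Adjusted p-values of lists are from camera with the preset correlation unless given. Of 7 neutrophil-attracting CXC chemokines 6 rose (median 3.00, adjusted p = 7.8e-10), including CXCL1 (4.09), CXCL6 (3.36) and CXCL2 (3.00). The 3 CXCR3-ligand chemokines, which attract T cells, all rose (median 3.08, adjusted p = 7.9e-07), with CXCL11 at 3.08 and CXCL9 at 2.29. Of 13 CC and other chemokines 10 rose and 1 fell (adjusted p = 1.1e-07), including CX3CL1 (2.75) and CCL8 (1.73). Of 15 interleukins and colony-stimulating factors 14 rose and 1 fell (median 1.38, adjusted p = 2.8e-15), with IL6 at 3.11, LIF at 2.81, IL1A at 2.65 and TNFSF13B, which encodes a B cell survival factor, at 2.50.

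All 31 interferon-stimulated genes rose (median 2.49, adjusted p = 2.8e-44, and 0.0017 with an estimated correlation), among them IFIT2 (3.66), MX1 (3.53) and MX2 (3.49). Of 14 genes of antigen processing and presentation 13 rose and 0 fell (median 0.86, adjusted p = 5.9e-18, and 0.0008 with an estimated correlation), including the transcription factor gene IRF1 (2.43), the peptide transporter genes TAP1 (1.75) and TAP2 (1.38) and PSMB9 (1.37). Of 15 adhesion molecules 10 rose and 2 fell (adjusted p = 1.9e-07), with ICAM1 at 3.61, VCAM1 at 2.03 and SELE at 1.51. Of 16 apoptosis regulators 9 rose and 4 fell (adjusted p = 3.8e-05), including BCL2A1 (2.06) and FAS (1.26). Of 15 genes of prostaglandin synthesis and receptors 5 rose and 2 fell (adjusted p = 0.0015), including PTGES (2.29) and PLA2G4A (1.64).

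Of 13 genes of zinc handling and metallothioneins 12 rose and 1 fell (median 0.80, adjusted p = 1.7e-12), with the zinc importer genes SLC39A8 at 3.17 and SLC39A14 at 1.53. Of 25 Wnt, BMP and bone remodelling genes 14 rose and 5 fell (adjusted p = 3.4e-06), including INHBA (2.40), FST (1.34), BMP6 (1.31) and TNFRSF11B, the gene of osteoprotegerin (1.24). Of 6 transcription regulators and receptors studied with these data 5 rose (adjusted p = 0.00022), with NFKBIZ at 2.28, STAT4 at 1.88, STAT3 at 0.29 and ELF3 at 0.18. This list was chosen by the study, so its count is not independent evidence.

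For 9 further lists the call with the preset correlation was lost with an estimated correlation. Of 22 immediate early genes 14 rose and 5 fell, led by the nuclear receptor genes NR4A3 (3.96) and NR4A2 (3.09) (adjusted p = 0.092 with an estimated correlation). Of 21 matrix metalloproteinases and their inhibitors 12 rose and 4 fell, and 13 rose and 4 fell when adjusted over the list alone, with the collagenase gene MMP1 at 3.63, MMP3 at 2.38 and the aggrecanase genes ADAMTS5 at 2.23 and ADAMTS4 at 2.22 (adjusted p = 0.091 with an estimated correlation). Of 30 genes of glycolysis and hypoxia response 21 rose and 4 fell, with the glucose transporter genes SLC2A1 at 2.15 and SLC2A6 at 1.41 and with ANGPTL4 at −1.66 (adjusted p = 0.061 with an estimated correlation). Of 17 IL-17 receptor signalling and response genes 8 rose and 4 fell, including ZC3H12A (1.46) and ARID5A (1.35) (adjusted p = 0.054 with an estimated correlation). Of 13 TNF receptor signalling genes 7 rose and 4 fell, with RIPK2 at 2.35 and the receptor gene TNFRSF1A at −0.52 (adjusted p = 0.14 with an estimated correlation).

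Of 16 cholesterol synthesis genes 11 rose and 2 fell, and 11 rose and 3 fell when adjusted over the list alone, with STARD4 at 1.36 and HMGCS1 at 0.87 (adjusted p = 0.15 with an estimated correlation). Of 14 complement components and regulators 8 rose and 2 fell, with CFB at 2.29 and C3 at 0.61 (adjusted p = 0.14 with an estimated correlation). Of 20 angiogenic and other growth factors 9 rose and 5 fell, with EREG at 1.95 and IGF1 at 1.24 (adjusted p = 0.14 with an estimated correlation). Of 16 contractile and myofibroblast genes 3 rose and 10 fell, and 4 rose and 10 fell when adjusted over the list alone, with LMOD1 at −1.09, CNN2 at −0.76 and TGFB2 at 0.95 (adjusted p = 0.29 with an estimated correlation). It was the only list called in the direction of a fall. In media itself 5 of the 16 rose and 1 fell at 18 h against untreated cells, with LMOD1 at 1.02 at 18 h and 1.63 at 72 h. Without 24 h, the time at which TNF arrays had low weights, 4 of 16 cholesterol genes, 2 of 17 IL-17 receptor signalling and response genes, 3 of 22 immediate early genes and 3 of 25 Wnt, BMP and bone remodelling genes fell with TNF.

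The other lists were not called with TNF. Of 30 collagens and other matrix genes 9 rose and 13 fell, 10 and 13 when adjusted over the list alone (adjusted p = 0.78), with COL14A1 at −0.55 and THBS1 at 0.41. Of 32 genes of cell cycle and DNA replication 7 rose and 4 fell, 6 and 3 when adjusted over the list alone and 4 and 5 without 24 h, and the median of −0.01 differed in sign from the test (adjusted p = 0.62). Oxidative stress genes divided, 5 rising and 9 falling of 16 (6 and 9 when adjusted over the list alone, adjusted p = 0.72), with SOD2 at 1.66 and HMOX1 at −1.33. Of 17 genes of the unfolded protein and integrated stress response 9 rose and 6 fell (adjusted p = 0.12), with DDIT4 at 1.01 and TRIB3 at −0.69, and of 10 heat shock genes 1, DNAJA1, rose (0.84) and 7 fell (adjusted p = 0.30).

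None of the 10 marker lists was called with TNF as deposited. Of fibroblast markers 3 rose and 7 fell of 12 (adjusted p = 0.30, and 0.045 after quantile normalization), with PDPN at 1.09 and PDGFRB at −0.54, of lining markers 2 rose and 1 fell of 6 (0.44), and of sublining markers 4 rose and 3 fell of 7 (0.12), with CD34 at 0.95 and CXCL12 at −0.88. Single markers of other cell types moved. The Fc receptor chain gene FCER1G rose by 1.44 among 15 macrophage markers, of which 3 rose (adjusted p = 0.17). IL7R rose by 2.13 as the only called T cell marker of 11 (adjusted p = 0.18), and TEK rose by 1.33 among 10 endothelial markers, of which 2 rose and 1 fell (adjusted p = 0.30). Of 8 B cell and plasma cell markers 1 rose and 1 fell (0 and 1 when adjusted over the list alone, adjusted p of about 1.0), with a median of 0.01 and a mean of −0.04. Of 7 mural markers 1 rose and 3 fell (adjusted p = 0.66), of 6 neutrophil and mast cell markers 1 rose (0 when adjusted over the list alone, adjusted p = 0.78), and of 7 chondrocyte markers 0 rose and 2 fell (adjusted p = 0.67).

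The response to TNF had early and late genes. At 1 h, 351 genes were higher and 59 lower, led by CCL20 (5.37) and CXCL8 (5.30), and EID3 had the largest fall (−1.28, SE 0.15 to 0.24, n = 2 arrays per arm). CXCL8 then stayed between 6.36 and 6.63 from 4 to 72 h, TNFAIP3 stayed between 3.24 and 4.01 from 1 to 72 h, and NFKBIZ was highest at 1 h (3.02) and at 1.81 at 72 h. At 1 h 15 of 17 genes of NF-kB feedback and family members and 16 of 22 immediate early genes had risen. None of the 31 interferon-stimulated genes rose at 1 h and 4 fell (12 when adjusted over the list alone), and all 31 rose at 4, 8, 18, 24 and 72 h, with medians of 1.93, 3.60, 3.49, 3.46 and 2.90. CXCL10 was at 0.64 at 1 h, where it was not called, reached 7.38 at 8 h and was at 3.48 at 72 h. The differences of MMP1 and IL6 from media were 1.34 and 2.09 at 1 h and 6.27 and 4.71 at 72 h, while in media itself MMP1 was at −2.01 and IL6 at −1.09 at 72 h against untreated cells at 0 h. STAT4 was at −0.03 at 1 h and 3.29 at 72 h. At 72 h the largest rises were in IBSP, which encodes bone sialoprotein (6.41), and CXCL8 (6.36), and the largest fall was in SLC14A1 (−5.86, SE 0.11 to 0.18).

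The difference between late (18 and 24 h) and early (1 and 4 h) effects of TNF was itself called for 5234 genes, 2229 with a larger and 3005 with a smaller or more negative late effect. It was largest for the interferon-induced antiviral genes BST2 (5.00 ± 0.16), MX2 (4.90) and RSAD2 (4.25), and most negative for SLC14A1 (−4.29), ADH1B (−3.31) and CMKLR1 (−3.27). The number of genes called with TNF was 4030 at 4 h, 4726 at 8 h, 6685 at 18 h, 6369 at 24 h and 5530 at 72 h. A fit to only the groups compared gave 183 at 1 h and 3968 at 24 h. At 4 h the count was 2443 without replicate 1 of media and 2419 without replicate 2 of TNF. The falls outnumbered the rises at these times as deposited (1374 higher and 2656 lower at 4 h, 2556 and 4129 at 18 h), and after quantile normalization (1596 and 2492 at 4 h, 2702 and 4029 at 18 h). Median centring gave 1935 and 1674 at 4 h, 2353 and 2324 at 8 h and 3567 and 3424 at 18 h, and kept more falls at 24 h (2815 and 3598) and 72 h (2749 and 2801).

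**Figure D1:**
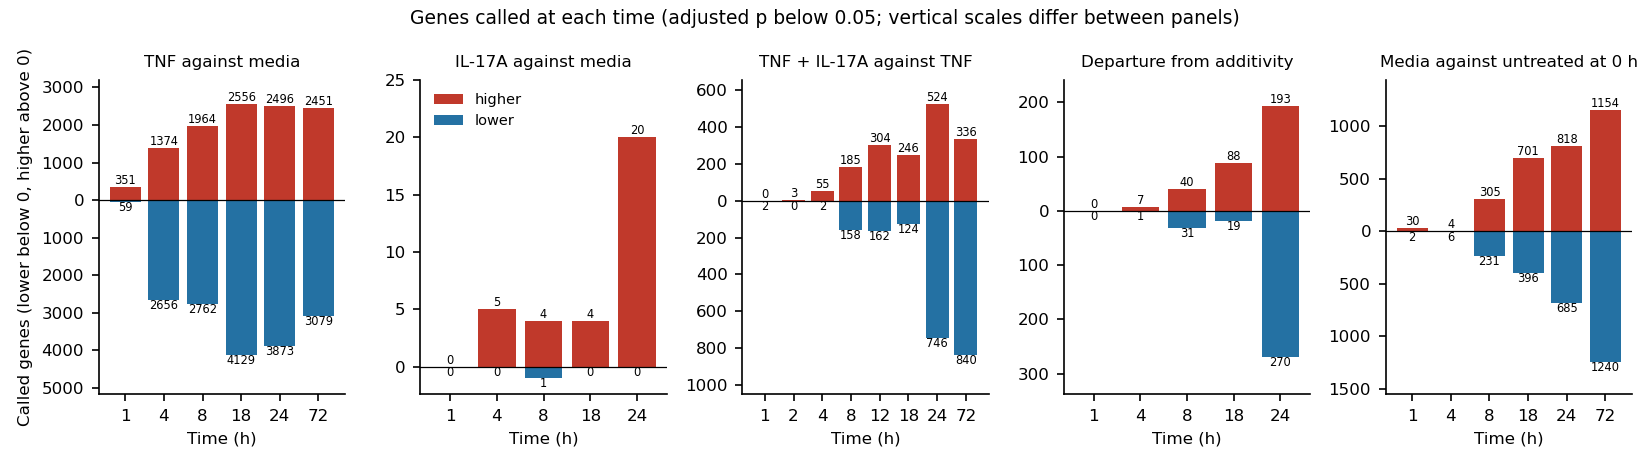
Number of genes called (adjusted p below 0.05) at each time in hours, with higher genes above 0 and lower genes below 0, in 5 panels for TNF against media, IL-17A against media, TNF plus IL-17A against TNF, the departure from additivity and media against untreated cells at 0 h, with vertical scales that differ. TNF changed 410 genes at 1 h and 6685 at 18 h, IL-17A alone at most 20, and IL-17A added to TNF 57 at 4 h and 1270 at 24 h.

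The second comparison asked what IL-17A did alone. Its changes were few and small. NFKBIZ, which encodes a cofactor of NF-kB, rose by 0.98 ± 0.04 (n = 10 arrays per arm, adjusted p = 1.9e-18), CXCL1 by 0.74 ± 0.06, IL6 by 0.65 ± 0.05, CXCL6 by 0.61 ± 0.07, the hormone gene STC1 by 0.55 ± 0.08, TNFAIP6 by 0.54 ± 0.04, CXCL8 by 0.48 ± 0.07 and MMP1 by 0.43 ± 0.04. Each of these 8 genes was higher at 5 of 5 times. In total 36 genes rose and 1 fell, none by 2-fold, and 1245 had an unadjusted p below 0.05. The gene that fell was RNASE8 (−0.22 ± 0.05, adjusted p = 0.049), whose adjusted p over alternatives that keep all arrays ran from 0.039 to 0.80 and which lost its call without any 1 of 16 of the 20 arrays. With the spread of the effect between times as the error, 2 genes were called, NFKBIZ and CXCL1, and a fit to only the groups compared called 24.

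At single times limma called 0 genes at 1 h, with 1862 at an unadjusted p below 0.05. At 1 h an intensity trend with a robust prior, or leaving out dim genes, gave 1 gene, and leaving out replicate 1 or replicate 2 of media gave 44 and 13. At 4 h the 5 called genes, chosen after their values were seen, were NFKBIZ (0.95), CXCL1 (0.74), IL6 (0.59), the ribonuclease gene ZC3H12C (0.57) and the kinase gene MAP3K8 (0.49). At 8 h they were NFKBIZ (1.04), CXCL1 (0.72), IL6 (0.62), ZC3H12C (0.56) and H2AC14 (−1.04), and at 18 h NFKBIZ (0.98), CXCL6 (0.92), TNFAIP6 (0.72) and MMP1 (0.53). At 24 h 20 genes were called, with NFKBIZ at 1.38, CXCL6 at 1.20, IL6 at 1.14 and CXCL1 at 1.11. A limma fit to only the groups compared called 1, 0, 0 and 2 genes at 4, 8, 18 and 24 h, with 729 and 1402 at an unadjusted p below 0.05 at 8 and 18 h, and array weights gave 1, 16 and 31 at 8, 18 and 24 h. The counts also moved by over 1.5 times when 1 array was left out. At 4 h 2 genes were called without replicate 1 of media and 1 without replicate 2 of IL-17A. At 8 h 279 were called without replicate 2 of media, 2 without replicate 1 of media and 1 without either array of IL-17A. At 18 h 7 were called without replicate 1 of media and 2 without either array of IL-17A, and at 24 h 8 without replicate 1 of media, 11 without replicate 1 and 8 without replicate 2 of IL-17A.

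Of 7 neutrophil-attracting CXC chemokines 3 rose with IL-17A (CXCL1, CXCL6 and CXCL8), and 4 when adjusted over the list alone (median 0.24, adjusted p = 4.8e-10). Of 17 IL-17 receptor signalling and response genes 3 rose, and 5 when adjusted over the list alone (adjusted p = 1.8e-10), the ribonuclease gene ZC3H12A (0.42) and RC3H1 (0.16) beside NFKBIZ. Of 13 genes of zinc handling and metallothioneins 2 rose, SLC39A14 (0.30) and SLC39A8 (0.30), and 6 when adjusted over the list alone (adjusted p = 1.3e-10). Of 15 genes of prostaglandin synthesis and receptors PTGS2 rose (0.43), and 2 rose when adjusted over the list alone (adjusted p = 0.0015). Of the 6 regulators and receptors studied with these data, a list that is not independent evidence, NFKBIZ alone rose (adjusted p = 1.9e-06). These 5 lists were also called with an estimated correlation. None of the CXCR3-ligand chemokines was called (CXCL9 at 0.10, CXCL11 at −0.06, list adjusted p = 0.91), and of 13 CC and other chemokines 0 were called, 1 when adjusted over the list alone (adjusted p = 0.31).

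With the preset correlation 15 more lists were called with IL-17A, with medians between −0.06 and 0.07, and each lost its call with an estimated correlation (adjusted p of 0.051 or more). Quantile normalization also ended the call of NF-kB feedback genes (adjusted p = 0.071), oxidative stress genes (0.23), sublining markers (0.12) and collagens (0.73), whose direction turned. T cell and macrophage markers lost their call under both scalings. Glycolysis and hypoxia genes had a median of 0.06, and 12 of 30 rose when adjusted over the list alone but 0 over all genes (adjusted p = 0.051 with an estimated correlation). Interferon-stimulated genes had a median of −0.06 with 0 of 31 called (adjusted p = 0.39 with an estimated correlation), and cell cycle genes a median of 0.07 with 0 of 32 called (0.40 in the same test). NF-kB feedback genes had 2 rises, NFKBIA (0.22) and REL (0.18), and 3 when adjusted over the list alone (adjusted p = 0.36 with an estimated correlation). MAP3K8 rose by 0.36, SOD2 by 0.28 and C3 by 0.21 as the single called members of TNF receptor signalling, oxidative stress and complement. Of the complement genes 2 rose when adjusted over the list alone.

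The third comparison asked what IL-17A changed in cells that also received TNF. The largest rise over 8 times was in COXFA4L3 (1.31 ± 0.08, n = 16 arrays per arm), a gene related to a cytochrome c oxidase subunit. CXCL6 rose by 1.12 ± 0.06, the cationic amino acid transporter gene SLC7A2 by 1.06 ± 0.05, CXCL2 by 1.01 ± 0.05, the epithelial transcription factor gene ELF3 by 1.01 ± 0.05, the lipid transporter gene ABCA8 by 0.85 ± 0.05, the endothelin receptor gene EDNRB by 0.83 ± 0.05 and CXCL1 by 0.82 ± 0.05. The largest falls were in CXCL11 (−0.87 ± 0.08), ANKRD1 (−0.76 ± 0.07), CXCL9 (−0.64 ± 0.06) and TNFSF15, a TNF family member gene (−0.62 ± 0.03). At 24 h CXCL6 was at 5.36 in media, 6.56 with IL-17A, 9.27 with TNF and 11.48 with both, ELF3 at 5.62, 5.48, 5.67 and 7.50, and CXCL11 at 7.77 with TNF and 5.48 with both.

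In total 810 genes rose and 1235 fell when IL-17A was added to TNF, 5 of them by at least 2-fold. Median centring gave 1107 higher and 1084 lower, and quantile normalization 1155 and 1317. With the spread of the effect between times as the error 8 genes were called, COXFA4L3, CXCL1, CXCL2, ELF3, NFKBIZ and ZC3H12A as rises and SNORD104 and TMEM229B as falls, the last 2 chosen after their values were seen, so that CXCL6, SLC7A2, ABCA8, EDNRB and the 4 largest falls lost their call. Without the times with low array weights (2, 8, 24 and 72 h) 755 genes were called.

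Chemokines of different kinds went apart. Of 7 neutrophil-attracting CXC chemokines 5 rose and 0 fell (median 0.51, adjusted p = 3.1e-14), among them CXCL3 (0.51) beside CXCL6, CXCL2 and CXCL1. All 3 CXCR3-ligand chemokines fell (median −0.64, adjusted p = 1.8e-08), with CXCL10 at −0.53. Without the times with low array weights 4 of 7 rose (median 0.36) and 3 of 3 fell (median −0.57). Of 13 CC and other chemokines 4 rose and 2 fell (adjusted p = 0.31), with CCL8 at 0.82, CCL20 at 0.56, CCL7 at 0.34 and CX3CL1 at −0.56. Of 15 interleukins and colony-stimulating factors 8 rose and 3 fell, 9 and 3 when adjusted over the list alone (median 0.25, adjusted p = 4.4e-07), including the granulocyte colony-stimulating factor gene CSF3 (0.57), IL1A (0.56), IL11 (0.51) and TNFSF13B (−0.45), and 6 rose and 1 fell without the low-weight times. Of 17 IL-17 receptor signalling and response genes 8 rose and 1 fell, 9 and 2 when adjusted over the list alone (adjusted p = 8.0e-08), including ZC3H12A (0.71), NFKBIZ (0.48) and STEAP4 (0.37). Of the 6 regulators and receptors studied with these data 4 rose (adjusted p = 5.4e-08, not independent evidence), with STAT4 at 0.23 and CUX1 at 0.10 beside ELF3 and NFKBIZ, and 2 of 6 rose without the low-weight times.

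Genes of antigen processing and presentation fell, 9 of 14 and 12 when adjusted over the list alone (median −0.12, adjusted p = 9.0e-10), with PSMB9 at −0.27, IRF1 at −0.25, PSME2 at −0.22 and TAP1 at −0.19. Without the times with low array weights 3 of 14 fell. Of 31 interferon-stimulated genes 0 rose and 12 fell, 16 when adjusted over the list alone, with BST2 at −0.49, IFIT2 at −0.34, MX2 at −0.33 and ISG15 at −0.25. That list's call was lost with an estimated correlation (adjusted p = 0.20), and without the low-weight times 1 of 31 fell. IFIT2 was at −0.23 without replicate 2 of TNF plus IL-17A at 72 h. Of 15 adhesion molecules 6 fell, with VCAM1 at −0.34, ICAM2 at −0.29 and ICAM1 at −0.21, and 1 rose and 6 fell when adjusted over the list alone (adjusted p = 0.050 with an estimated correlation, not below the threshold). Without the low-weight times 1 of the 15 fell.

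For 7 further lists the call of TNF plus IL-17A against TNF was also lost with an estimated correlation. Of 16 contractile and myofibroblast genes 1 rose and 6 fell, 1 and 9 when adjusted over the list alone, with CCN2 at −0.37, CCN1 at −0.33 and TGFB2 at 0.33 (adjusted p = 0.11 with an estimated correlation), and 1 rose and 3 fell without the low-weight times. Cell cycle genes fell for 7 of 32, 12 when adjusted over the list alone, with CCNB2 at −0.20 and PLK1 at −0.19 (adjusted p = 0.39 with an estimated correlation), and 0 of 32 fell without the low-weight times. Of 16 oxidative stress genes 1 rose and 6 fell, with TXNRD1 at −0.23 and SLC7A11 at −0.20 (adjusted p = 0.22 with an estimated correlation), and 1 rose and 1 fell without those times. Of 17 genes of the unfolded protein and integrated stress response 2 rose and 6 fell, with DDIT4 at 0.36, PPP1R15A at −0.33 and ASNS at −0.27 (adjusted p = 0.47 with an estimated correlation, and 0.063 after quantile normalization). Zinc handling genes rose for 4 of 13, 6 when adjusted over the list alone, with SLC30A1 at 0.18 (adjusted p = 0.18 with an estimated correlation), and for 2 without the low-weight times. Of 16 cholesterol synthesis genes 1 rose and 4 fell, 1 and 6 when adjusted over the list alone (adjusted p = 0.38 with an estimated correlation), and of 16 apoptosis regulators likewise 1 rose and 4 fell, 1 and 6 when adjusted over the list alone (adjusted p = 0.22 with an estimated correlation, and 0.053 after quantile normalization). When those times were left out 1 cholesterol gene and 0 apoptosis regulators fell, 1 of each list rose, and neither list was called (adjusted p = 0.34 and 0.35).

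Lists that were not called when IL-17A was added still held called members. Among 25 Wnt, BMP and bone remodelling genes 7 rose and 7 fell, 8 and 7 when adjusted over the list alone (adjusted p = 0.41), with BMP6 at 0.65, INHBA at 0.50, SFRP1 at 0.48 and the Wnt inhibitor gene DKK1 at −0.56. Among 20 growth factors 7 rose and 3 fell, 7 and 4 when adjusted over the list alone (adjusted p = 0.057), with IGF1 at 0.54 and FGF5 at −0.30. Of 30 glycolysis and hypoxia genes 6 rose and 2 fell, 7 and 3 when adjusted over the list alone (adjusted p = 0.052). Of 22 immediate early genes 7 rose and 5 fell, 8 and 5 when adjusted over the list alone (adjusted p = 0.36), with NR4A2 at 0.51. Of 17 NF-kB feedback genes 1 rose and 3 fell, 1 and 6 when adjusted over the list alone (adjusted p = 0.21), with REL at 0.35 and NFKBIE at −0.33. Of 21 metalloproteinases and inhibitors 5 rose and 1 fell, 6 and 5 when adjusted over the list alone (adjusted p = 0.23), with MMP3 at 0.23, and MMP1 was at −0.08 and not called. Without the low-weight times 4 rose and 4 fell of the Wnt and BMP genes, 7 and 2 of the growth factors and 5 and 1 of the glycolysis and hypoxia genes, both lists then called (adjusted p = 0.032 and 0.0014), 1 and 1 of the NF-kB feedback genes and 1 and 0 of the metalloproteinases. None of the 10 marker lists was called.

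The number of genes called when IL-17A was added to TNF differed between times. The counts were 2 at 1 h, 3 at 2 h, 57 at 4 h, 343 at 8 h, 466 at 12 h, 370 at 18 h, 1270 at 24 h and 1176 at 72 h. A limma fit to only the arrays compared gave 0 at 1 and 2 h, with 876 and 1935 at an unadjusted p below 0.05, and 31, 8, 161, 66, 324 and 79 from 4 to 72 h, so that 8 h lay below 4 h. Array weights gave 15 at 1 h, 0 at 2 h (1770 unadjusted), 199 at 8 h, 683 at 24 h and 620 at 72 h. At 24 h 524 were higher and 746 lower (771 and 618 after median centring, 763 and 851 after quantile normalization), and at 72 h 336 and 840 (463 and 655 after median centring, 512 and 733 after quantile normalization). Leaving out any 1 of the 4 arrays compared moved the count by over 1.5 times at 1 h (0 to 1), 2 h (0 to 1176), 4 h (21 to 89), 8 h (59 to 1136), 12 h (200 to 296) and 72 h (453 to 2743). The highest values came without replicate 2 of TNF plus IL-17A at 2 and 8 h and without its replicate 1 at 72 h. At 18 h the count was 146 without replicate 2 of TNF, 175 without replicate 1 and 203 without replicate 2 of TNF plus IL-17A, and at 24 h 773 without replicate 1 of TNF plus IL-17A.

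The genes that led changed with time. At 2 h ZC3H12A (0.68), NFKBIZ (0.53) and OR6A2 (0.66) were called, of which OR6A2 lost its call without any of 3 arrays and ZC3H12A without either array of TNF. At 4 h IL1A (1.63) and NR4A2 (1.52) led, and at 8 h CXCL6 (1.36) and CCL20 (1.34), with CXCL9 at −1.10. At 12 h GPR183, an oxysterol receptor gene (1.56), and EDNRB (1.53) led, with RGS16 at −1.02, and at 18 h EDNRB (1.46) and PRKAR2B (1.44). CXCL10 was at −1.23 at 18 h, a call lost without replicate 2 of TNF or replicate 1 of TNF plus IL-17A. At 24 h ABCA8 (2.56) and COXFA4L3 (2.25) rose most and CXCL11 (−2.28) fell most, and at 72 h SLC7A2 (2.46), COXFA4L3 (2.29) and TRPA1 (−2.06). The 2 genes called at 1 h were SNORD114-26 (−1.06), which lost its call without any of 3 arrays, and SNORD36B (−1.03). CXCL6 went from −0.07 at 1 h to 2.21 at 24 h and ELF3 from 0.09 to 1.83, while NFKBIZ stayed between 0.26 and 0.74. Late minus early effects were called for 880 genes, the most positive being ABCA8 (1.98), SLC7A2 (1.61) and CXCL6 (1.52) and the most negative TRPA1 (−1.29), CXCL11 (−1.26) and BST2 (−1.24). A fit to only the groups compared called 490. Without the low-weight times, which left 18 h against 1 and 4 h, 193 were called. In it TRPA1, CXCL11 and BST2 were at −0.63, −0.63 and −0.58 and not called. This drops 24 and 72 h, where CXCL11 and TRPA1 had the largest falls. Low-weight arrays and the choice of times therefore cannot be told apart.

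**Figure D2:**
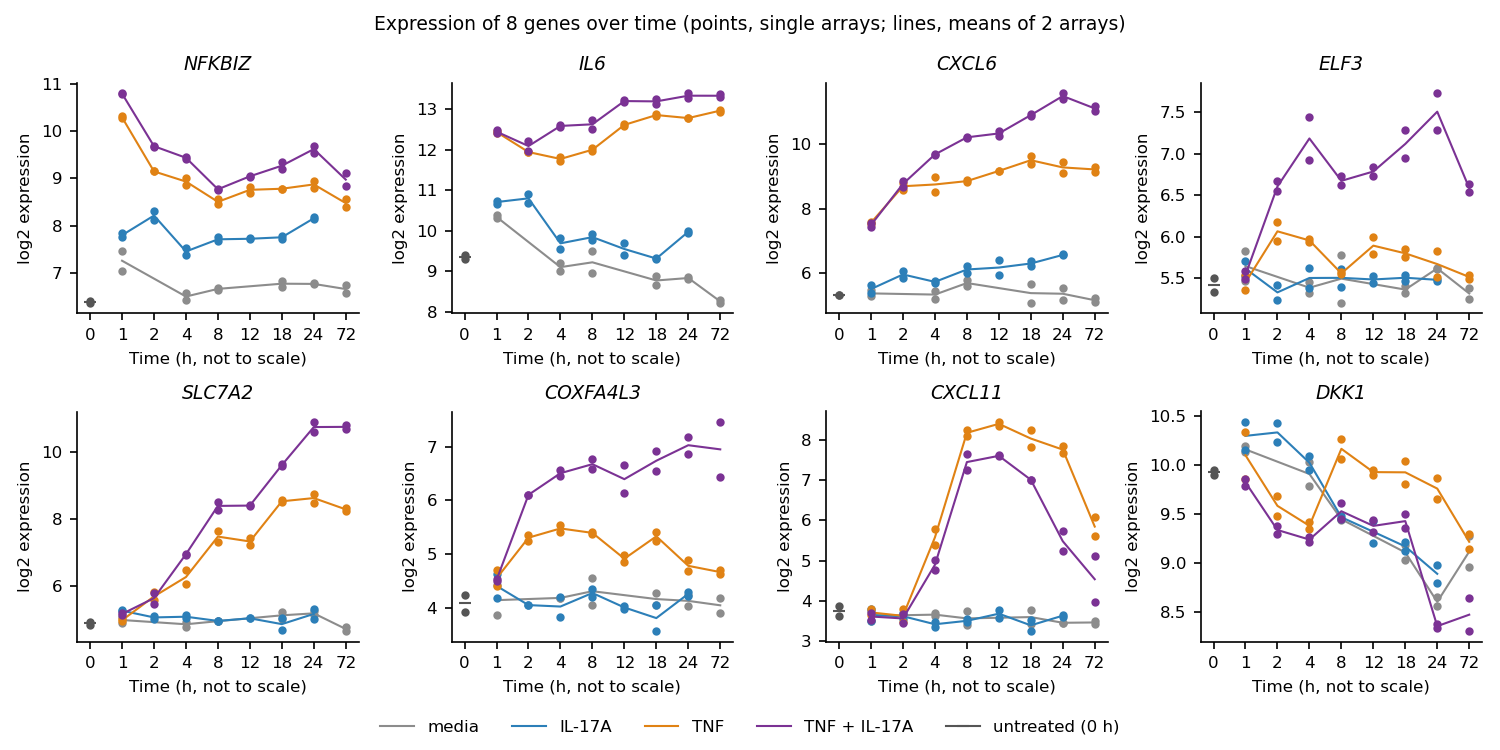
Log2 expression of 8 genes (vertical axes) at 0 to 72 h (horizontal axes, not to scale) in untreated cells, media, IL-17A, TNF and TNF plus IL-17A, with points for single arrays and lines for means of 2 arrays. CXCL6 reached 11.48 with both cytokines at 24 h against 9.27 with TNF, SLC7A2 10.75 against 8.29 at 72 h, and CXCL11 stood at 5.48 against 7.77 at 24 h.

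**Figure D3:**
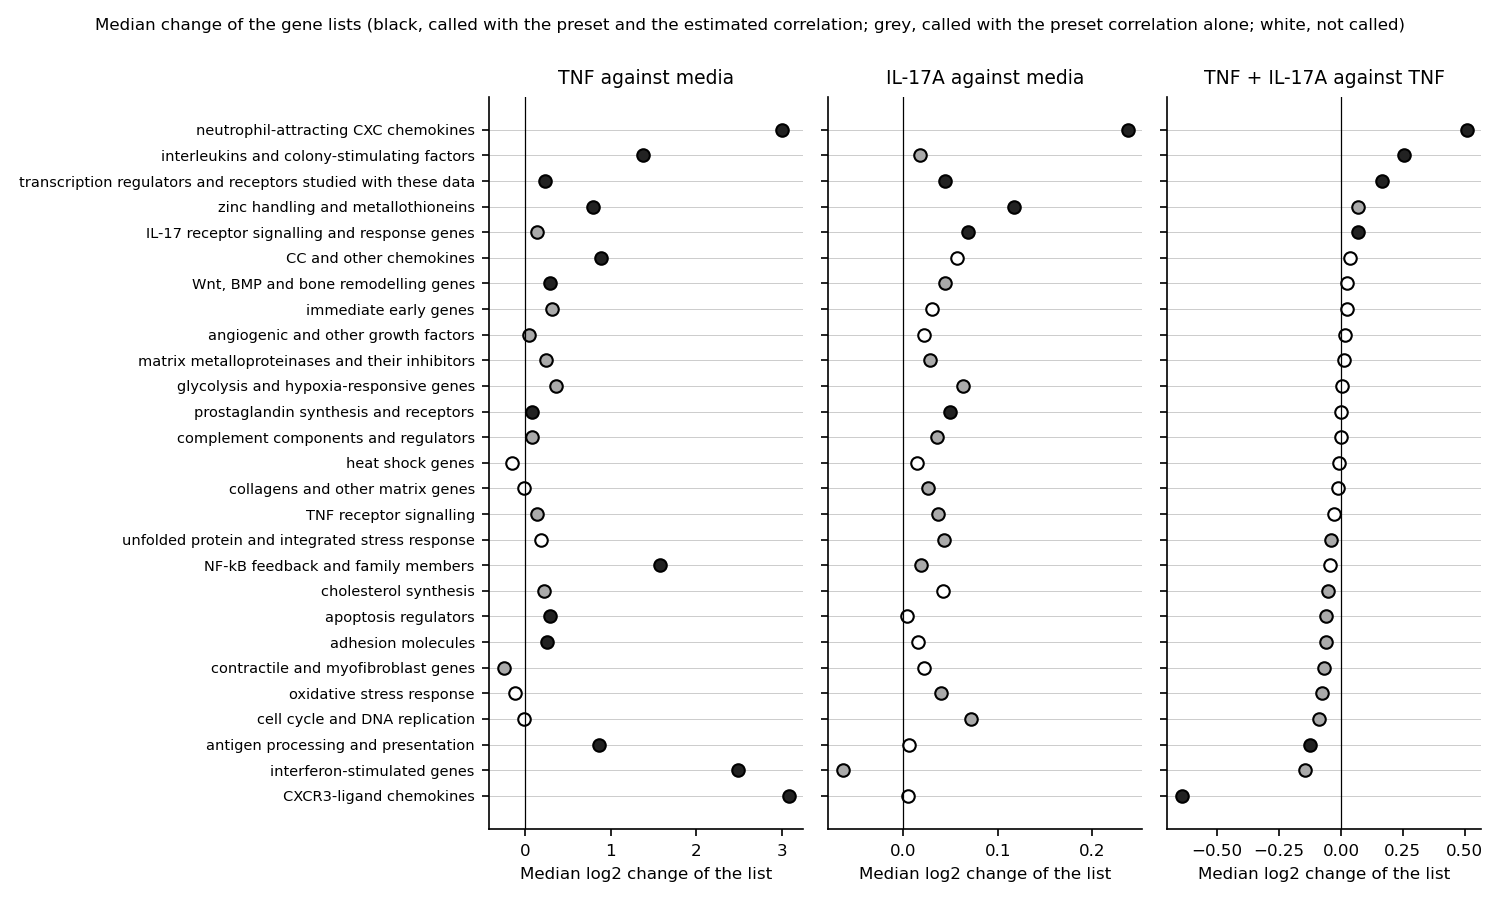
Median log2 change of each gene list, cell type markers left out (horizontal axes), for TNF against media, IL-17A against media and TNF plus IL-17A against TNF; black points were called with the preset and the estimated correlation, grey points with the preset correlation alone and white points were not called. Neutrophil-attracting CXC chemokines lay at 3.00, 0.24 and 0.51, and CXCR3-ligand chemokines at 3.08, 0.00 and −0.64.

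The fourth comparison asked whether the log2 change with both cytokines was more or less than the sum of their separate log2 changes. A sum of log2 changes is a product of fold changes, so whether the fold changes themselves added up was not tested. The change with both exceeded the sum most for COXFA4L3 (1.22 ± 0.14, n = 10 arrays per arm), ELF3 (1.10 ± 0.10), SLC7A2 (0.95 ± 0.08), CXCL2 (0.85 ± 0.10), the thiamine transporter gene SLC19A3 (0.83 ± 0.08), ABCA8 (0.83 ± 0.09), EDNRB (0.82 ± 0.09) and CCL8 (0.79 ± 0.14). It fell short of the sum most for CXCL11 (−0.90 ± 0.14), ANKRD1 (−0.86 ± 0.13), CXCL9 (−0.86 ± 0.10) and DKK1 (−0.71 ± 0.08). NFKBIZ and MMP1, which rose with each cytokine alone, were each at −0.48, so that their log2 change with both was less than the sum of the log2 changes. For CXCL1 and IL6 no departure was called (0.07 and −0.18). Changes of dim genes are understated, and ELF3 at 24 h lay below the array medians in media, with IL-17A and with TNF. For such genes understated changes with the single cytokines could alone place the change with both above the sum, which was not tested.

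In total 183 genes departed above the sum and 222 below (239 and 209 after median centring, 287 and 266 after quantile normalization), and 2027 had an unadjusted p below 0.05. With the spread of the effect between times as the error limma called 0 genes. It gave 380 at an unadjusted p below 0.05, fewer than the share of 0.05 expected without any change. A departure that changes with time raises this error, so the count of 0 does not show that departures were absent. Without the low-weight times, here 8 and 24 h, 28 were called, and CXCL2 (0.51), ABCA8 (0.38), CCL8 (0.68), CXCL11 (−0.46), ANKRD1 (−0.49), CXCL9 (−0.56) and DKK1 (−0.41) were no longer among them.

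Of the neutrophil-attracting CXC chemokines 3 of 7 departed above the sum, 3 above and 1 below when adjusted over the list alone (adjusted p = 3.2e-05), with CXCL6 and CXCL3 both at 0.55, and all 3 CXCR3-ligand chemokines departed below it (median −0.86, adjusted p = 5.6e-10), with CXCL10 at −0.68. Without the low-weight times 0 of 7 and 0 of 3 were called, and both lists kept their call. These were the 2 lists called with both correlations. With the preset correlation alone, interleukins and colony-stimulating factors lay above (3 above and 2 below of 15, 7 and 3 when adjusted over the list alone, IL23A at 0.60, adjusted p = 0.092 with an estimated correlation). Antigen processing genes lay below (0 above and 3 below of 14, 5 below when adjusted over the list alone, adjusted p = 0.051 with an estimated correlation), as did 5 others of the 10 called lists, and growth factors lay above (4 above and 2 below of 20, IGF1 at 0.51, adjusted p = 0.33 with an estimated correlation). Without the low-weight times 0 interleukin, 0 antigen processing and 1 growth factor genes were called, and the growth factor list lost its call (adjusted p = 0.10), as did adhesion molecules (0.25). NF-kB feedback (0.012), Wnt and BMP (0.028), heat shock (0.028) and glycolysis and hypoxia genes (0.032) were then called below the sum.

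At 1 h limma called 0 departures, with 1142 genes at an unadjusted p below 0.05, and 3, 8 and 1 without replicate 1 of media, replicate 2 of media and replicate 2 of TNF. At 4 h 8 genes were called, CXCL2 (1.44), NR4A2 (1.36), IL1A (1.32), IL1B (1.20), ELF3 (1.11), SEMA6D (0.77), OSGIN2 (0.48) and KBTBD12 (−0.83), a set chosen after its values were seen. The counts were 71 at 8 h, 107 at 18 h and 463 at 24 h (193 above and 270 below, 264 and 236 after median centring, 304 and 320 after quantile normalization). A limma fit to only the groups compared called 1, 0, 8 and 121 at 4, 8, 18 and 24 h, with 1455 genes at an unadjusted p below 0.05 at 8 h, where the other settings that keep all arrays gave 32 (array weights) to 163 (quantile normalization). Leaving out any 1 of the 8 arrays gave 1 to 5 at 4 h and 19 to 586 at 8 h, where 528 were called without replicate 2 of media and 586 without replicate 2 of TNF plus IL-17A. At 18 h 40 were called without replicate 2 of TNF and 55 to 65 without either array of media or IL-17A or replicate 2 of TNF plus IL-17A, and at 24 h 304 without replicate 1 of TNF plus IL-17A.

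Genes that rose with IL-17A alone did not all rise when it was added to TNF. Of the 8 largest, CXCL6 (1.12), CXCL1 (0.82), NFKBIZ (0.48), IL6 (0.43), STC1 (0.22) and CXCL8 (0.20) rose again, whereas TNFAIP6 (0.04) and MMP1 (−0.08) were not called. Of all 36 genes 19 also rose in the presence of TNF and 2, CH25H and PLK2, fell, both chosen after their values were seen.

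**Figure D4:**
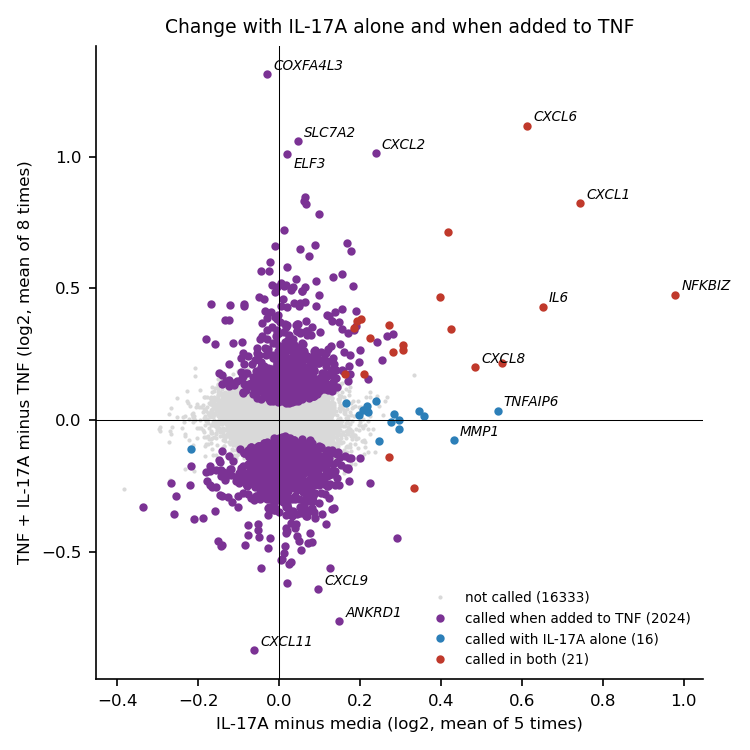
Log2 change of each tested gene with IL-17A alone against media (horizontal axis, mean of 5 times) and with TNF plus IL-17A against TNF (vertical axis, mean of 8 times), coloured by the comparison in which the gene was called. NFKBIZ lay at 0.98 and 0.48, CXCL6 at 0.61 and 1.12, and COXFA4L3 at −0.03 and 1.31.

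Against media, TNF plus IL-17A changed 8516 genes, 3067 higher and 5449 lower (4640 and 4173 after median centring, 3300 and 5378 after quantile normalization), and 1265 with the spread between times as the error. Of 7 neutrophil-attracting CXC chemokines 6 were higher (median 4.09), with CXCL8 at 6.45 ± 0.07, CXCL1 at 4.91 ± 0.06 and CXCL6 at 4.52 ± 0.07. Genes outside the lists were not ranked in this comparison. CXCL10, CXCL11 and CXCL9 were at 4.70, 2.11 and 1.53, and all 31 interferon-stimulated genes rose (median 2.41), led by RSAD2 (4.00). Set directly against each other over 7 times, TNF and IL-17A differed in 9953 genes, 3674 higher and 6279 lower with TNF (6014 and 5089 after median centring, 3844 and 5945 after quantile normalization), and 6429 genes with the spread between times as the error. The difference was 5.73 for CXCL8, 5.40 for CCL20 and 1.21 for NFKBIZ.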

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

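The late against early comparisons and the first 8 counts of other splits of the arrays were planned, the tests of probe sets without a single gene name were not among the planned comparisons, and the tests of explanations, the values without the low-weight times and the splits that kept the arms with TNF apart were chosen after the results were seen. The genes below passed an adjusted limma test of the difference itself. No group held 4 to 10 arrays, so single arrays were not tested against their group.

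For TNF against media, the late effect (18 and 24 h) differed from the early effect (1 and 4 h) for 13 of the 14 genes tested, with SE of 0.11 to 0.27 on the log2 scale. Late minus early effects were above 0 for BST2 (5.00), MX2 (4.90), RSAD2 (4.25), TRPA1 (3.74), CCL5 (2.38), CXCL10 (2.13), GBP4 (2.03), PTGS2 (0.86) and CXCL8 (0.67). They were below 0 for SLC14A1 (−4.29), ADH1B (−3.31), CMKLR1 (−3.27) and TRIB2 (−1.58). BST2 and MX2 were among these genes only because this difference was large.

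For IL-17A added to TNF, the late effect (18, 24 and 72 h) differed from the early effect (1, 2 and 4 h) for all 14 genes tested. It was higher late for ABCA8 (1.98), SLC7A2 (1.61), CXCL6 (1.52), COXFA4L3 (1.38), EDNRB (0.91), ELF3 (0.79), CXCL2 (0.68) and CXCL1 (0.63), and lower late for TRPA1 (−1.29), CXCL11 (−1.26), BST2 (−1.24), ANKRD1 (−1.18), TNFSF15 (−1.17) and CXCL9 (−0.62). TRPA1 and BST2 were among the 14 only because this difference was large. Without the times with low array weights, which left 18 h against 1 and 4 h, TRPA1, CXCL11 and BST2 were at −0.63, −0.63 and −0.58. They lost their call, but this is a comparison of other times.

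Probe sets outside the named genes also carried signal. With TNF, 1580 of the 12,083 probe sets with no gene name were called, 779 higher and 801 lower, and 612 of the 1754 with several names, 175 higher and 437 lower. When IL-17A was added to TNF, 102 with no name and 63 with several were called. Probe sets 8045695 and 7943413 had no gene name and rose with TNF by 4.96 ± 0.08 and 3.84 ± 0.05, and 7924461 and 7925452 fell by 1.46 and 1.31. The only probe set with no name called with IL-17A alone was 8045695 (0.59 ± 0.08).

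More of the called genes fell than rose with TNF. As deposited 35.2% of the called genes were higher, against 49.3% after median centring and 37.4% after quantile normalization. Median centring shifts all genes of an array alike, so its share does not test whether the excess of falls is real. The arrays hold no measure of total RNA, and for this reason scaling and a true excess of falls cannot be told apart.

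The CXCR3 ligands CXCL9, CXCL10 and CXCL11 were lower when IL-17A was added to TNF (median −0.64). The highest median under the 2 other scalings was −0.63, and the highest without any 1 of 32 arrays was −0.61. Neither test could decide the cause. The median change of all genes in this comparison was 0.0008 as deposited, 0.0129 after median centring and 0.0019 after quantile normalization, so these scalings shifted it little. A mean over 8 times also moves little when 1 array is left out. The values show only that the fall was kept under these settings. A biological effect of IL-17A on these genes is a hypothesis that the technical tests leave open, found and tested on the same data from 1 donor. The spread between donors was not measured.

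More genes were called late than early when IL-17A was added to TNF. Some late groups held arrays of low weight, but at 12 and 18 h, where no compared array had a weight below 0.5, the smaller count was 370 against 57 at 4 h. Leaving out 1 array gave as few as 146 at 18 h, without replicate 2 of TNF, and as many as 89 at 4 h, without replicate 1 of TNF. With only the arrays compared in the fit, the smallest count of 12, 18 and 24 h was 66 against 31 at 4 h. In the same fit 8 h had 8, and 72 h had 79 in place of 1176. Such a fit leaves only 2 residual degrees of freedom, and the times were chosen after the results were seen. It therefore cannot decide how far the shared error estimate made the difference. A response that builds up with time is a candidate explanation, not separated here from differences between the cultures taken at each time.

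The arrays within each time were also split in other ways, 100 splits per comparison with the real one included. The real grouping called the most genes for TNF against media (8398 genes against at most 5258 in the others), IL-17A against media (37 against 25), TNF plus IL-17A against media (8516 against 7847), TNF plus IL-17A against TNF (2045 against 1039) and TNF against IL-17A (9953 against 8829), where only 1 split, the real one, reached the real count. The splits also separate the 2 technical replicates of a group, which raises the error whenever such replicates resemble each other. The real grouping can then lead without an effect of treatment. These counts therefore do not exclude chance or differences between separately treated cultures. With the spread between times as the error IL-17A against media had 2 called genes and TNF plus IL-17A against TNF 8, although effects that change with time raise that error. For the departure from additivity 7 of 100 splits called at least the real 405 genes, up to 5893, so chance was not excluded. Splits that call several times the real count point to a structure of the samples, here arms with TNF mixed with arms without it. In 100 splits that kept the arms with TNF apart, an addition made after the first test was seen, 1 split, the real one, called 405 and the highest other called 128. These splits separate technical replicates too, so the same limit holds. For late against early effects the splits were too few for a share under 0.05, with 880 against 552 over 10 splits for IL-17A added to TNF and 5234 against 1121 over 3 splits for TNF.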

How the results depend on the processing

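Leaving out the times with low array weights was chosen after the data were seen, and the other alternatives were planned. No called change of a named gene reversed. With median centring the majority of calls turned from lower to higher for TNF plus IL-17A against media (4640 higher and 4173 lower), TNF against IL-17A (6014 and 5089), TNF plus IL-17A against TNF (1107 and 1084) and the departure (239 and 209), and with quantile normalization for the departure alone of these (287 and 266). The direction of the collagen list with IL-17A turned with quantile normalization. Counts that moved by over 1.5 times are given, and the others stayed within that, and the cause of a change was not tested except where fewer arrays or another error term were used. A trend with a robust prior gave 1, 8 and 10 genes for IL-17A at 1, 4 and 8 h, 8 for TNF plus IL-17A against TNF at 2 h, 117 departures at 8 h and 24 for media at 4 h. Leaving out dim genes gave 1 for IL-17A at 1 h, 5 for TNF plus IL-17A against TNF at 1 h, 128 departures at 8 h, 29 for media at 4 h and 13 gene lists for IL-17A. Median centring gave 3 for IL-17A at 8 h. Quantile normalization gave 5 for TNF plus IL-17A against TNF at 1 h, 163 departures at 8 h, and 49, 48 and 812 for media at 1, 4 and 8 h. Array weights gave 1, 16 and 31 for IL-17A at 8, 18 and 24 h, 3397 for TNF plus IL-17A against media at 8 h, 15, 0, 199, 683 and 620 for TNF plus IL-17A against TNF at 1, 2, 8, 24 and 72 h, 5 and 32 departures at 4 and 8 h, and 103, 1922, 2586 and 3620 for media at 4, 18, 24 and 72 h. An estimated correlation left 13, 5, 6 and 2 gene lists called for TNF, IL-17A, TNF plus IL-17A against TNF and the departure, against 22, 20, 15 and 10. A fit to only the groups compared, with fewer arrays for the error, gave 24 for IL-17A over 5 times, 490 for late against early with IL-17A added, 183 and 3968 for TNF at 1 and 24 h, 1, 0, 0 and 2 for IL-17A at 4, 8, 18 and 24 h, 148, 2801 and 4285 for TNF plus IL-17A against media at 1, 8 and 72 h, 0, 0, 31, 8, 161, 66, 324 and 79 for TNF plus IL-17A against TNF from 1 to 72 h, 1, 0, 8 and 121 departures at 4, 8, 18 and 24 h, and 0, 0, 70 and 677 for media at 1, 4, 8 and 18 h. Where limma gave 0 in that fit, from 729 to 1935 genes had an unadjusted p below 0.05, and from 1416 to 1770 where array weights gave 0. With arrays averaged and the spread between times as the error, TNF had 2032 called genes, IL-17A 2, TNF plus IL-17A 1265 against media and 8 against TNF, the departure 0 (limma, 380 at an unadjusted p below 0.05) and TNF against IL-17A 6429. With untreated cells as the control, IL-17A had 669 over 5 times and 76, 75, 401, 1315 and 1811 at single times, which includes the change of media with time, and TNF plus IL-17A had 560 at 1 h. Without the times with low array weights TNF plus IL-17A against TNF had 755 and the departure 28. Late against early with IL-17A added, then 18 h against 1 and 4 h, had 193. Results for named genes lost their call in 143 of 369 with the spread between times as the error, 58 of 381 with low-weight times left out and 15 of 414 with only the groups compared. The mean of a gene's probe sets changed no call.

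Leaving out 1 array at a time, where the lone array of a group was assumed to vary like those of other groups, gave these lowest and highest counts where the count moved. Media gave 22 to 63, 5 to 5, 217 to 973, 654 to 832, 916 to 1025 and 1489 to 1761 at 1, 4, 8, 18, 24 and 72 h. TNF at 4 h gave 2419 to 4025. IL-17A gave 0 to 44, 1 to 4, 1 to 279, 2 to 7 and 8 to 16 at 1, 4, 8, 18 and 24 h. The departure gave 0 to 8, 1 to 5, 19 to 586, 40 to 105 and 304 to 627 at the same times. TNF plus IL-17A against TNF gave 0 to 1, 0 to 1176, 21 to 89, 59 to 1136, 200 to 296, 146 to 264, 773 to 1450 and 453 to 2743 from 1 to 72 h. Counts over several times moved less, with 7903 to 8765 for TNF, 30 to 52 for IL-17A, 1766 to 2503 for TNF plus IL-17A against TNF and 332 to 548 for the departure. Of 9468 refits for named genes 190 lost and 47 gained a call.

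With the replicate number as a block, TNF against media had 8395 called genes and TNF plus IL-17A against TNF 2034, all 49 counts stayed within 1.5 times, and 4 named genes gained a call. The replicate numbers did not pair the arrays in a constant way. Over 435 pairs of groups the differences between replicates correlated at a median of 0.0012 (−0.54 to 0.53), with 93 pairs above 0.1. Single pairs far from 0 in either direction show that some groups shared a difference between arrays that the numbers do not label. The block could not remove such a difference. The array signal limits what dim genes can show, and 10,603 of 18,417 genes were above the array median on at least 2 arrays.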

Other observations

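The test of a hypothesis in this part was chosen after the results were seen, and the comparisons of media with untreated cells were planned.

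Cells in media alone also changed over the time course, in which time in culture and time in low serum went together. Against untreated cells at 0 h, media changed 32 genes at 1 h, 10 at 4 h, 536 at 8 h, 1097 at 18 h, 1503 at 24 h and 2394 at 72 h. A limma fit to only the groups compared called 0, 0, 70 and 677 at 1, 4, 8 and 18 h, with 879 and 1300 at an unadjusted p below 0.05 at 1 and 4 h. Quantile normalization gave 49, 48 and 812 at 1, 4 and 8 h, array weights 103, 1922, 2586 and 3620 at 4, 18, 24 and 72 h, and at 4 h a trend with a robust prior gave 24 and leaving out dim genes 29. No test of whole lists was made for media. Of 32 cell cycle and DNA replication genes 17 rose at 8 h, 20 when adjusted over the list alone, and at 18 h 20 rose and 12 fell (median 1.11), the same counts as adjusted over the list alone. The mitotic genes KIF20A (2.14), PLK1 (1.79), CCNB1 (1.61) and AURKA (1.59) rose at 18 h, while the DNA replication genes CCNE2 (−1.42), CDC6 (−1.01), MCM5 (−0.78) and CDC45 (−0.76), chosen after their values were seen, fell. At 72 h 0 rose and 26 fell (median −0.66), with CCNE2 at −1.71 and MCM5 at −1.30. At 72 h 17 of the 32 were lower with TNF than in media (20 when adjusted over the list alone, median −0.40). Immediate early genes rose for 9 of 22 in media at 1 h, and 15 when adjusted over the list alone, but none of the 22 was called at 1 h in the fit to only the groups compared.

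At 72 h in media the largest rises were in PDGFRL (3.32), CLCA2 (3.15) and ADH1B (3.04), and the largest falls in AOC2 (−2.55), DTL (−2.13) and HMCN1 (−2.05), with SE of 0.11 to 0.16 and 2 arrays per arm. Of 30 collagens and other matrix genes 4 rose and 16 fell (5 and 19 when adjusted over the list alone), with ELN at −1.81, POSTN at −1.48 and COL15A1 at −1.32. Of 16 contractile and myofibroblast genes 8 rose and 2 fell (9 and 2 when adjusted over the list alone), with LMOD1 at 1.63 and ACTA2 at 0.61. The medians of these lists kept their sign under both scalings. Leaving out 1 array moved these counts by over 1.5 times. At 1 h 63 genes were called without replicate 1 of media, at 4 h 5 without any of the 4 arrays, and at 8 h 304 without replicate 1 and 973 without replicate 2 of media and 223 and 217 without replicate 1 and 2 of the untreated cells. At 18 h the count was 654 without replicate 2 of media and 659 and 689 without replicate 1 and 2 of the untreated cells. At 24 h it was 916, 944 and 928 without the same arrays, and at 72 h 1586 without replicate 2 of media and 1489 without replicate 2 of the untreated cells.

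A hypothesis was that the responses to IL-17A with and without TNF share genes. Of 36 genes higher with IL-17A alone and 810 higher when it was added to TNF, 19 were in both, against 1.58 for independent lists (Fisher's exact test over 18,417 genes, two-sided, p = 5.8e-17). The 2 comparisons share no arrays. Genes that respond together are not independent, and the expected overlap counts all tested genes, dim ones included. The p-value can therefore overstate the evidence. Across all tested genes, which are not independent replicates, the changes were not correlated upward (Pearson r −0.03, Spearman rho −0.14). The responses may thus share a small set of genes.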
